A study of Mus musculus with 16 samples.

How the data were processed

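RNA from 16 samples of cultured dorsal root ganglia was measured on Illumina Mouse Ref-8 v2.0 BeadChips, per the submitters' study description. Per the labels' protocols, lentivirus was added on day 4 in culture, spot cultures were cut with a blade on day 7 and collected 3 h or 12 h later, and uninjured cultures were collected on day 7. Total RNA was isolated with a column kit, its quality was read on a Bioanalyzer, and it was linearly amplified and labelled with biotin, per the labels' protocols. The knockdown used MISSION hairpins against HIF-1α, and human HIF-1α cDNA was placed in the FUGW vector, per the submitters' study description. GenomeStudio is named in the submitters' processing notes, and its version and settings are not given in the sources used here.

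The deposited series table holds intensity values for 25697 probes, with a column named for each sample. No source used here states how the authors made these intensities beyond naming GenomeStudio. The deposited values themselves have the form of linear intensities after background subtraction and quantile normalization between arrays: they run from -21.7 to 40784.5, 27.2% lie below 0, and the upper quartile and the maximum are the same on all arrays. A second deposited file holds values before normalization, in 32 columns (16 of signal and 16 of detection p) whose names match no sample label. These 32 columns were not used, and only that file's column of gene symbols was. Symbols were brought up to date with a table of RefSeq genes of the assembly GRCm38.p6: 20733 probes carried a current symbol, 3872 were updated from a synonym that belongs to a single gene, and 1092 kept their own.

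The plan written before the data were examined assumed signal with detection p for each sample, and named a fallback for values that were already corrected. The fallback was used. The deposited values were background-corrected with the normexp model and an offset of 50, quantile-normalized and put on the log2 scale with limma 3.58.1 in R 4.3.3. As no detection p could be given to a sample, a probe was kept if its deposited intensity was above 16 on at least 2 of the 16 arrays. With a background SD of 6.42, estimated from the values below 0, 16 lies 2.49 SDs above 0, a one-sided tail of 0.638%. Between 47.8% and 47.9% of probes were above 16 on each array, and median intensity was 13.3 to 13.5, so signal over background limits what can be read of dim genes. This filter kept 15086 probes. The probe with the highest mean stood for each gene, which left 11151 genes, 663 of them with clone or locus names that were counted and not named in the text. An exploratory run with values floored at 16 or raised by 50 had shown its counts of called genes before the offset and this filter were settled.

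All 16 arrays entered 1 limma fit with a mean for each of the 9 groups, 7 residual degrees of freedom and 13.2 prior degrees of freedom, so groups with 1 array borrow the spread of the others. Knockdown and overexpression were each compared with control at each time and averaged over the 3 times. Injury at 3 h and 12 h was compared with uninjured in control cultures, and its interaction with each construct was tested with limma's F test over both times. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Fold bounds ("at least") take 16 in place of a group that was not above 16 on any array. The text names, by a rule written before the data were examined, Hif1a, the 8 genes with the largest rise and the 8 with the largest fall among those called (filled up to 4 by the smallest p where fewer were called), and up to 4 members of each gene list with the smallest p; other genes named are stated as chosen later.

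The 17 gene lists were written from general knowledge before the data were examined: HIF targets of glycolysis and glucose transport, other HIF targets, injury-induced and regeneration-associated genes, immediate early genes, amino acid and endoplasmic reticulum stress genes, sensory neuron genes, Schwann cell and satellite glia, fibroblast, endothelial and macrophage markers, cell cycle, interferon response, NF-κB cytokine, cholesterol synthesis, heat shock, p53 target and oxidative phosphorylation genes. Each was tested with limma's camera at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the 68 tests of 17 lists in 4 comparisons. Of these 17 passed with the preset and 0 with the estimated correlation. The size of the correlation is not the only source of this loss. In knockdown the injury-induced list had an estimated correlation of -0.00838, below the preset. Its unadjusted camera p still went from 0.00220 with the preset to 0.0111 with the estimate. List tests of the interactions were adjusted over 68 tests of their own, and those of contrasts added later over the 17 lists of each contrast. The correlation of knockdown and overexpression differences was set beside 100 simulations with no effect and the same control arrays.

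The steps were tested on simulated data made from these arrays' means and spreads. For a log2 change of 1, limma recovered 76.1% of the changed genes in the knockdown average (70 of 92, with 6 false calls), 86.3% in the overexpression average, 64.2% in knockdown at 3 h, 66.3% in uninjured overexpression, 67.7% for injury at 3 h and 79.2% for injury at 12 h. For a log2 change of 0.5 it recovered 63.5%, 55.8%, 35.5%, 11.0%, 40% and 23.7% of them in the same order. Alternatives to the offset, background step, normalization, filter, choice of probe and block were tried, and each array was left out in turn. Raw signal without background correction, median scaling of it, filters on detection p and a block for the BeadChip were not run, since they need the unmatched columns or a chip name. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.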

Results

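Gene expression was measured in cultures of dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, taken from CD-1 mouse embryos at embryonic day 13. Cells were plated as a spot from which axons grow outward. On day 4 in culture they received a lentivirus carrying a control short hairpin RNA (shRNA), an shRNA against Hif1a (knockdown), or human HIF-1α (overexpression). HIF-1α is the oxygen-regulated subunit of a transcription factor that switches on genes for glycolysis, vessel growth and other responses to low oxygen. On day 7 the axons were cut with a blade, and RNA was collected from uninjured cultures or 3 h or 12 h after the cut. The 16 arrays fell into 9 groups, with 6 control, 6 knockdown and 4 overexpression arrays. Each group had 2 arrays except uninjured overexpression and overexpression at 12 h, which had 1 each. Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision. Differences below are on the log2 scale after background correction with an offset of 50, which understates the change of dim genes. After filtering, 11151 genes were tested.

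The arrays grouped by construct. On the first component, with 54.3% of the variance, knockdown and overexpression arrays lay at opposite ends. The second, with 34.2%, set the control arrays apart from both. Across genes, pairs of arrays of the same construct and time correlated at 0.994 to 0.996, pairs of the same construct at other times at 0.992 to 0.996, and pairs of different constructs at 0.918 to 0.954. Genes are not independent replicates, so these values only describe the arrays. No 2 arrays held identical values. The labels name no batch, and each construct is present as 1 cluster, so a culture or virus batch and the construct cannot be told apart in any comparison with control.

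**Figure D1:**
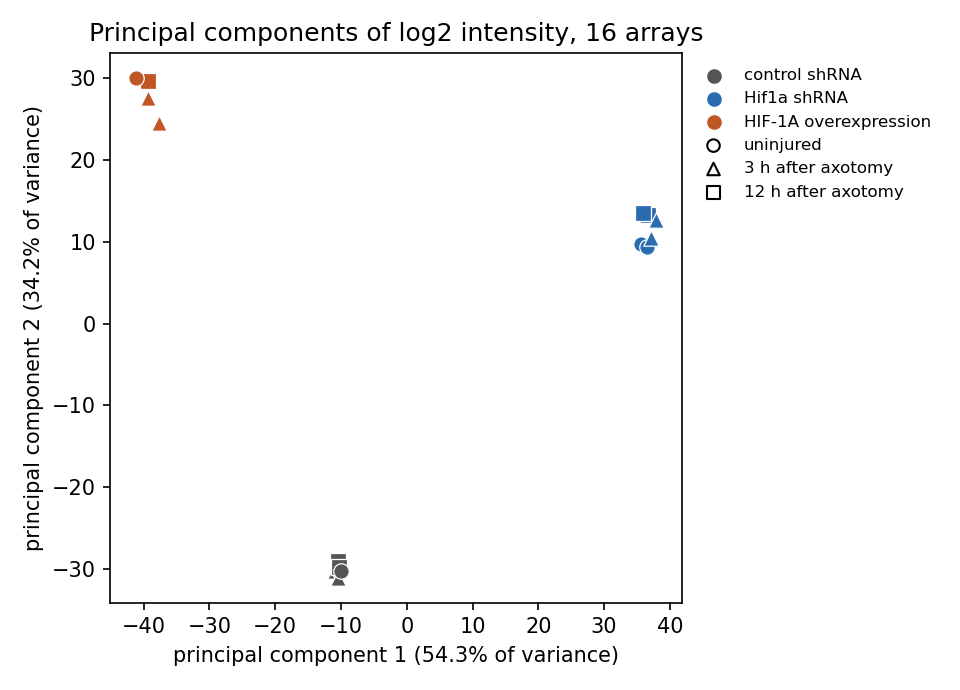
Each point is 1 of the 16 arrays, placed by its first (54.3% of variance) and second (34.2%) principal components of log2 intensity, in component units. Color marks the construct and shape the time, and the 3 constructs form separate clusters, with far smaller distances between times within each.

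The target of the knockdown was read first. The single mouse Hif1a probe tested (ILMN_2852034) was dim. Its deposited intensity averaged 30.0 ± 7.96 (SD, n = 6) in control cultures and was above the cutoff of 16 on 6 of 6 control arrays. It averaged -2.64 ± 3.76 (SD, n = 6) after knockdown and 0.72 ± 4.44 (SD, n = 4) under overexpression, above 16 on 0 of these 10 arrays. Hif1a fell by 0.59 in knockdown (SE 0.0685, adjusted p = 1.71e-07) and by 0.53 in overexpression (SE 0.0791, adjusted p = 8.49e-06; limma, Benjamini-Hochberg). It was at least 1.82-fold lower in both, a bound set by the cutoff. The overexpressed cDNA is human, and whether this mouse probe reads it is not known, so the probe does not check the overexpression label. Its fall in knockdown is what that label predicts. The like fall in overexpression means that the probe separates control from both others and cannot by itself check the knockdown label. In control cultures Hif1a differed from uninjured by 0.01 (SE 0.119, adjusted p = 0.995) at 3 h and by -0.09 (adjusted p = 0.939) at 12 h.

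**Figure D2:**
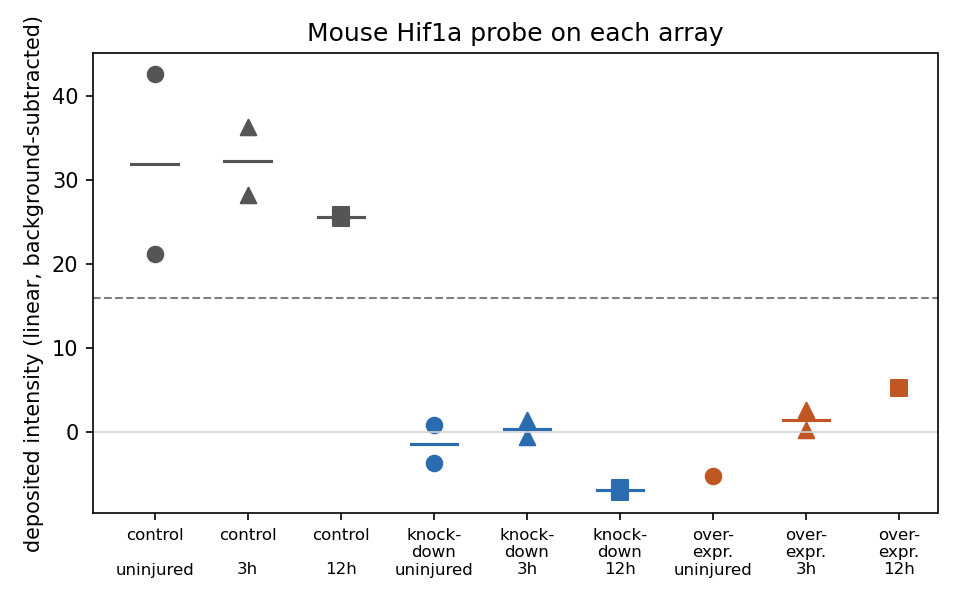
Deposited intensity (linear, background-subtracted) of the mouse Hif1a probe on each of the 16 arrays, by construct and time, with bars at group means and a dashed line at 16. Control arrays lie between 21.3 and 42.7 and the others between -7.15 and 5.22.

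The first comparison asked which genes differed between knockdown and control cultures, averaged over the 3 times. As construct and batch cannot be told apart, a difference does not show that a gene depends on HIF-1α. Phlda3, a p53-induced inhibitor of Akt signaling, was 28.9-fold higher (log2 difference 4.85, SE 0.0837, 6 arrays against 6), and Hspb1, a small heat shock protein induced in injured neurons, was 25.1-fold higher (4.65, SE 0.0710). The receptor tyrosine kinase Axl rose 19.4-fold, the receptor phosphatase Ptprv 17.2-fold, the urotensin-related peptide Uts2b 14.9-fold, the cytochrome oxidase isoform Cox6b2 14.3-fold, secretin (Sct) 13.9-fold, and Pidd1, a p53-induced death domain protein, 12.1-fold. The largest falls were in Pkia, an inhibitor of protein kinase A, which was 12.0-fold lower (-3.58, SE 0.0788), and in Ppif, the mitochondrial cyclophilin, 9.39-fold lower. Sub1, a transcriptional coactivator, was 8.61-fold lower, the nucleosome-binding protein Hmgn2 8.58-fold lower and Vamp2, a vesicle protein of the synaptic release machinery, 7.98-fold lower. Nudt19, Sptssa and Tmem14c fell by 2.84 each on the log2 scale. For these 16 genes the adjusted p was at most 3.46e-15, and all arrays of one group lay on the same side of the other group.

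HIF target genes moved both ways after knockdown. Of 19 measured genes of glycolysis and glucose transport, 12 fell, 2 rose and 5 did not pass (median -0.36). The triosephosphate isomerase Tpi1 fell by 1.12 (SE 0.0634), and the aldolases Aldoc and Aldoa fell by 0.95 and 0.62, while the glucose transporter Slc2a1 rose by 0.93 (SE 0.0690). As a set they were lower than other genes (limma's camera, adjusted p = 0.0391; adjusted p = 0.359 with an estimated correlation). This call was also lost without overexpression 3 h replicate 1 (adjusted p = 0.0517) or 2 (0.0539), without uninjured control replicate 1 (0.0554) without knockdown 3 h replicate 1 (0.0569), with deposited values floored at 16 (0.0691) and with probes kept only if above 16 on at least 8 arrays (0.0830). Of 28 other HIF targets, 10 rose and 10 fell. Ddit4, a stress-induced inhibitor of mTOR signaling, rose by 1.69, the collagen-modifying enzymes P4ha2 and Plod2 rose by 1.31 and 1.18, and the transferrin receptor Tfrc fell by 0.94. That list did not differ from other genes (median -0.01, mean 0.05, adjusted p = 0.983).

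Injury and stress genes mostly rose with the knockdown. Of 26 genes induced by nerve injury or tied to regeneration, 16 rose, 1 fell and 9 did not pass (median 0.29; adjusted p = 0.0115; adjusted p = 0.122 with an estimated correlation). Besides Hspb1, the neuropeptide galanin (Gal) rose by 1.36 (SE 0.102) and Vip was at least 6.04-fold higher, while the neuropeptide gene Adcyap1 fell by 2.52 (SE 0.0955). Of 15 immediate early genes, 10 rose and 0 fell (median 0.49; adjusted p = 0.00194; adjusted p = 0.122 with an estimated correlation). Egr1 rose by 3.18, Fos by 1.87 and Dusp1 by 1.37. Of 18 genes of amino acid and endoplasmic reticulum stress, 13 rose and 1 fell (median 0.52; adjusted p = 0.00143; adjusted p = 0.335 with an estimated correlation). Nupr1, a stress-induced chromatin protein, was at least 17.1-fold higher, and Trib3, a target of ATF4, rose by 1.08. Of 17 p53 targets, 15 rose and 1 fell (median 0.90; adjusted p = 3.98e-06; adjusted p = 0.0715 with an estimated correlation). They included Trp53inp1 (2.52), the death receptor Fas (2.42) and the cell cycle inhibitor Cdkn1a (1.83). Of 10 heat shock genes 3 rose and 3 fell. Bag3 rose by 2.31, and that list's median (-0.02) and mean (0.63) differed in sign (adjusted p = 0.502).

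Other lists changed in part or did not pass as sets. Of 15 cholesterol synthesis genes, 10 fell and 1 rose (median -0.29; adjusted p = 0.00648; adjusted p = 0.260 with an estimated correlation). The sterol carrier Stard4 fell by 2.81, and the enzymes Nsdhl and Msmo1 fell by 1.33 and 0.88. Of 20 sensory neuron genes 7 fell, 4 rose and 9 did not pass (adjusted p = 0.253). The peptides of pain fibers Calca (CGRP) and Tac1 (substance P) fell by 2.09 and 1.66, the nociceptor sodium channel Scn10a by 1.44 and peripherin (Prph) by 1.38. Of 26 oxidative phosphorylation genes 12 fell and 7 rose (adjusted p = 0.297). Sdhc, a subunit of complex II, fell by 1.44 (SE 0.0651). Of 9 fibroblast markers 6 rose and 1 fell (median 0.40; adjusted p = 0.0951), among them Pdgfra (1.84) and Dcn (1.13). Of 8 Schwann cell and satellite glia markers 2 rose and 3 fell (median 0.14, mean 0.00, camera direction down, adjusted p = 0.970). The signaling molecule Dhh was at least 6.15-fold higher and the neurotrophin receptor Ngfr fell by 1.19. Of 6 endothelial markers 2 rose (adjusted p = 0.449), of 7 macrophage markers 2 rose and 1 fell (median -0.08, mean 0.06, adjusted p = 0.984), and of 12 cell cycle genes 6 rose and 3 fell (adjusted p = 0.545). Of 8 NF-κB cytokine genes 5 rose and 1 fell (adjusted p = 0.102), with the adhesion molecule Icam1 7.14-fold higher. Of 11 interferon response genes 5 rose and 4 fell (median 0.16, mean -0.08, camera direction up, adjusted p = 0.960); Ifit3 fell by 2.46 and Irgm1 rose by 1.17.

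Over all genes, limma called 6653 of 11151 in the knockdown average at an adjusted p under 0.05 (Benjamini-Hochberg), 3492 higher and 3161 lower, and 556 and 416 of these differed at least 2-fold. Adjusted over the list alone, the counts of risen and fallen members became 3 and 12 for HIF glycolysis, 11 and 12 for the other HIF targets, 1 and 11 for cholesterol synthesis and 1 and 0 for endothelial markers, and were the same for the other 13 lists. Construct and any batch of cultures cannot be told apart here.

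The second comparison asked the same of cultures that overexpressed human HIF-1α. Espn, an actin-bundling protein, was 102-fold higher than in control (log2 difference 6.67, SE 0.0808, 4 arrays against 6), although 1 of its 4 probes went the other way. Mgarp, a HIF-induced protein of mitochondria, was 74.2-fold higher (6.21, SE 0.0911). The serotonin receptor Htr5b was at least 206-fold higher, the secreted peptide gene Prok2 at least 127-fold, the carbonic anhydrase Car12 at least 126-fold and the cell cycle regulator Rgcc at least 122-fold. Plekha2 rose 35.6-fold, and dermokine (Dmkn) was at least 139-fold higher on the probe tested, while 1 of its 3 probes went the other way. On this scale the largest fall was in Thy1, a surface glycoprotein of neurons, which was 14.1-fold lower (-3.82, SE 0.0874). The secreted protein Dkk3 was at least 20.8-fold lower, Lgi3 5.93-fold, the stem cell factor Kitl 5.11-fold, the synaptic vesicle protein Sv2b 4.99-fold, Sub1 4.70-fold and Rassf4 4.45-fold lower, and the neuronal G protein subunit Gng3 fell by 2.32 on the log2 scale. The adjusted p of these 16 genes was at most 3.06e-13.

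HIF targets rose as a group. Of the 19 glycolysis and glucose transport genes 15 rose, 1 fell and 3 did not pass (median 0.93; adjusted p = 2.41e-08; adjusted p = 0.0854 with an estimated correlation). The glucose transporters Slc2a1 and Slc2a3 rose by 3.27 (SE 0.0797) and 1.92, and the phosphofructokinase Pfkl by 2.50. Of the 28 other HIF targets 24 rose, 0 fell and 4 did not pass (median 1.21; adjusted p = 4.66e-14; adjusted p = 0.0586 with an estimated correlation). Besides Car12, the collagen crosslinking enzyme Lox was at least 58.6-fold higher, and Stc2 and the adenylate kinase Ak3l1 rose by 3.52 and 3.01. The overexpression cultures were also set directly against the knockdown cultures, a contrast added after the values were seen that does not use the control arrays. There 17 glycolysis genes were higher and 1 lower (adjusted p = 5.37e-09; adjusted p = 0.0526 with an estimated correlation), and 25 of the other targets were higher and 1 lower (adjusted p = 7.59e-11; adjusted p = 0.0352 with an estimated correlation). These were adjusted over the 17 lists of this contrast, not over 68 tests, so they cannot be set beside those against control. For the other targets the unadjusted camera p with an estimated correlation was 0.00207 here and 0.000862 against control.

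Immediate early and p53 genes rose here too. Of 15 immediate early genes 11 rose and 1 fell (median 0.71; adjusted p = 5.02e-05; adjusted p = 0.0770 with an estimated correlation), with Ier3 higher by 3.15, Junb by 2.73, Egr1 by 2.34 and Fos by 1.94. Of 17 p53 targets 12 rose and 2 fell (median 0.68; adjusted p = 8.17e-05; adjusted p = 0.0770 with an estimated correlation), with Phlda3 higher by 3.84, Trp53inp1 by 1.91, Cdkn1a by 1.90 and the cyclin Ccng1 by 1.75. Of 26 injury-induced genes 14 rose and 7 fell (adjusted p = 0.0528). Vip was at least 34.5-fold higher, Gal rose by 3.23 and the integrin Itga7 fell by 1.51. Of 18 amino acid and endoplasmic reticulum stress genes 7 rose and 2 fell (adjusted p = 0.0523), and Ddit3 rose by 1.80 while the serine synthesis enzyme Phgdh fell by 1.18. Of 10 heat shock genes 4 rose and 5 fell (median -0.39, mean 0.04, adjusted p = 0.958), with Bag3 higher by 1.48 and Hspa1a by 1.21. Of 8 NF-κB cytokine genes 4 rose and 1 fell (adjusted p = 0.0526), with complement C3 higher by 2.52. Of 11 interferon response genes 1 rose and 5 fell (adjusted p = 0.307). Ifit3 fell by 2.04, Ifit2 was at least 5.51-fold lower and Ifi35 rose by 1.30.

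Cholesterol synthesis genes fell. Of 15 measured, 10 fell and 2 rose (median -0.61; adjusted p = 0.0158; adjusted p = 0.308 with an estimated correlation). Dhcr7, the last enzyme of one branch of the pathway, was 3.02-fold lower (SE 0.0973 on the log2 scale), Mvd fell by 1.45 and Fdps by 1.03, and Lss rose by 1.08. Of 20 sensory neuron genes 9 fell and 6 rose (adjusted p = 0.472). The growth cone protein Stmn2 fell by 1.54 and Prph by 1.30, and the transcription factor Isl1 and the ATP-gated channel P2rx3 rose by 0.88 and 0.86. Of 26 oxidative phosphorylation genes 13 fell and 3 rose (adjusted p = 0.121), and the ATP synthase subunit Atp5b fell by 0.55. Of 8 Schwann cell and satellite glia markers 3 rose and 3 fell (median -0.00, mean 0.08, adjusted p = 0.960), and the myelin gene Pmp22 rose by 1.58 while Ngfr fell by 1.22. Of 9 fibroblast markers 4 rose and 3 fell (adjusted p = 0.449), and Twist2 rose by 1.20 while vimentin (Vim) fell by 0.47. Endothelial markers had 1 rise among 6 (adjusted p = 0.545), macrophage markers 1 rise and 3 falls among 7 (adjusted p = 0.769), and cell cycle genes 1 rise and 4 falls among 12 (adjusted p = 0.764).

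Over all genes, limma called 6161 of 11151 in the overexpression average at an adjusted p under 0.05 (Benjamini-Hochberg), 2881 higher and 3280 lower, and 537 and 386 of these differed at least 2-fold. With cyclic loess, a setting added after the data were seen, 3222 were higher and 2897 lower. Adjusted over the list alone, the counts of risen and fallen members became 14 and 8 for injury-induced genes, 6 and 11 for sensory neuron genes, 4 and 2 for NF-κB cytokines and 14 and 2 for p53 targets, and were the same for the other 13 lists. The control hairpin is the control for both constructs, so the overexpression vector has none of its own.

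**Figure D3:**
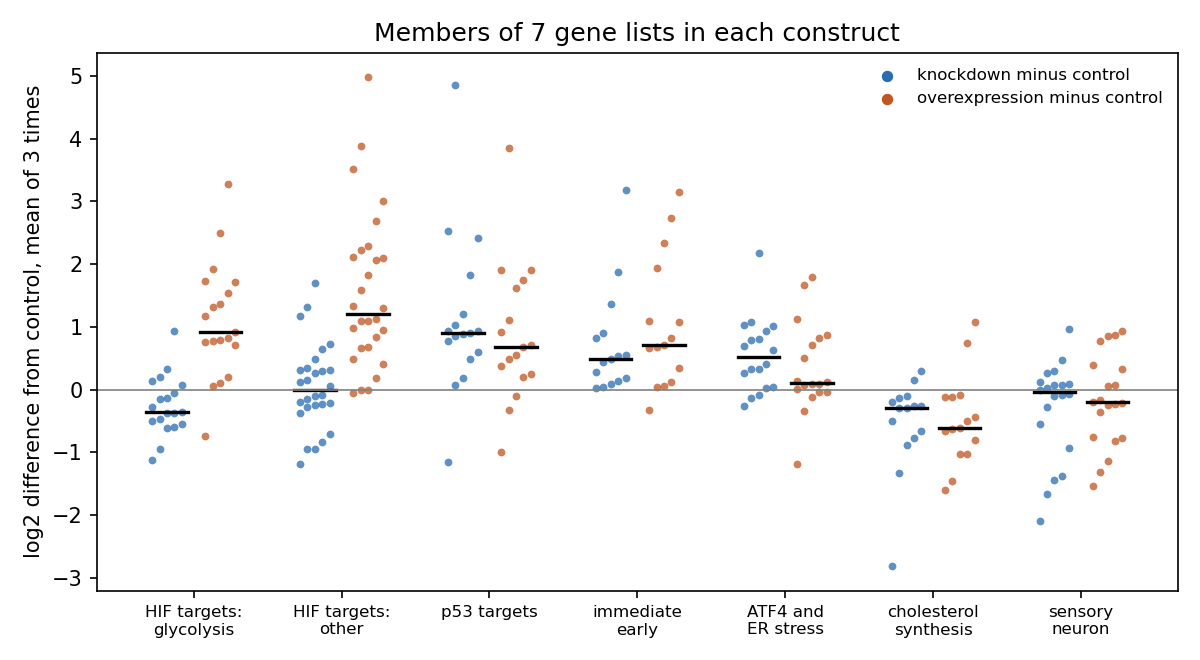
Each point is a measured gene of 1 of 7 lists, at its log2 difference from control averaged over the 3 times, for knockdown and overexpression, with bars at list medians. The other HIF targets have medians of -0.01 in knockdown and 1.21 in overexpression, and the p53 targets of 0.90 and 0.68.

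At single times the constructs gave similar pictures. Against control of the same time, knockdown changed 4489 genes when uninjured (2444 higher, 2045 lower), 4892 at 3 h (2585 and 2307) and 4720 at 12 h (2460 and 2260), with 2 arrays against 2. Of 3262 genes higher at any time 1844 were higher at all 3, and of 2966 lower 1551. Overexpression changed 3985 genes when uninjured (1845 higher, 2140 lower; 1 array against 2), 4325 at 3 h (2065 and 2260; 2 against 2) and 3852 at 12 h (1862 and 1990; 1 against 2). Of 2620 genes higher at any time 1339 were higher at all 3, and of 3013 lower 1364. In uninjured, 3 h and 12 h cultures the glycolysis list had medians of -0.27, -0.37 and -0.35 in knockdown and 1.16, 0.89 and 0.89 in overexpression. The other HIF targets had 1.40, 1.14 and 1.09 in overexpression. The comparisons with 1 array take their spread from the other groups and assume that the lone array varied like them.

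**Figure D4:**
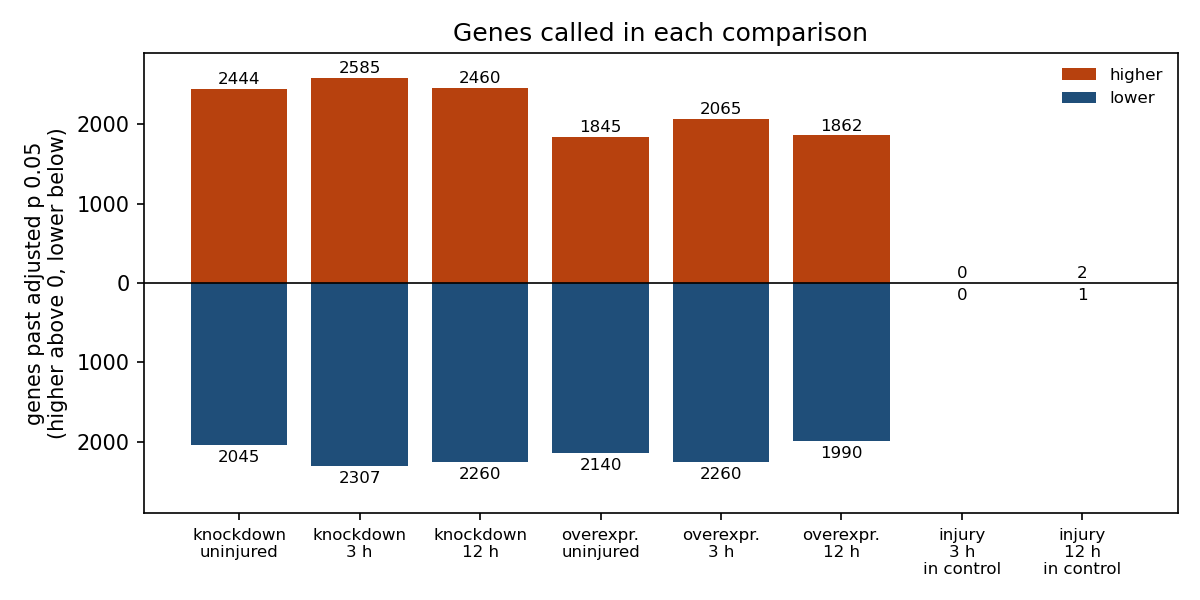
Bars count the genes of 11151 tested that passed an adjusted p of 0.05 in each comparison, higher above 0 and lower below. Each construct changed between 3852 and 4892 genes at a single time, and injury in control cultures changed 0 at 3 h and 3 at 12 h.

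Knockdown and overexpression were then set against each other, because opposite changes in HIF-1α could change genes in opposite directions or alike. Slc2a1 rose in both (0.93 and 3.27), as did Phlda3 (4.85 and 3.84) and Egr1 (3.18 and 2.34). Sub1 fell in both, by 3.11 and then by 2.23, and Prph fell by 1.38 and by 1.30. Thy1 rose by 1.81 in knockdown (SE 0.0757) and fell by 3.82 in overexpression. These examples were chosen after their values were seen. Among the called genes 1315 were higher in both and 1458 lower in both, where independent lists would share 902 and 930. Another 851 were higher in knockdown and lower in overexpression (1027 for independent lists), and 632 the reverse (817). Across genes the 2 differences correlated at 0.258 with a covariance of 0.0953, and at 0.240 and 0.0898 with the control arrays split by replicate number. Both share the control arrays. In 100 simulations with no effect the correlation averaged 0.433, and the covariance averaged 0.00296 and reached at most 0.00315, so the observed covariance exceeded what the shared controls gave by 0.0923. Genes are not independent replicates, and a batch of control cultures would also move both differences alike.

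Injury in control cultures was examined to find genes that respond to cutting the axon. At 3 h no gene passed, and the nearest were values only. Thy1 was higher by 0.79 (SE 0.131, adjusted p = 0.0724), the G protein subunit gene Gna14 by 0.91 (SE 0.161, adjusted p = 0.0841), and Lynx1, a modulator of acetylcholine receptors, by 0.68. Trrap differed by -0.77 (SE 0.147, adjusted p = 0.118), and Mkrn3 and Mvp by -0.58 each. Among the immediate early genes Egr1 differed by 0.49, Fos by 0.43 and Dusp1 by -0.47. That list had 0 of 15 members past the threshold but stood higher than other genes as a set (median 0.11; adjusted p = 0.0456; adjusted p = 0.260 with an estimated correlation). The other 16 lists did not pass, and none of their members did. Adjusted over the list alone, 1 of the other HIF targets and 1 of the amino acid and endoplasmic reticulum stress genes rose, 3 macrophage markers fell, and no other member passed. Lists whose median and mean differed in sign were heat shock (-0.01 and 0.02) and interferon response (0.00 and -0.01). The macrophage markers Lyz1, Laptm5 and Lyz2 had values of -0.82, -0.47 and -0.43.

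limma called 0 of 11151 genes at 3 h with Benjamini-Hochberg adjustment, and 684 had an unadjusted p under 0.05, with 2 arrays against 2. When limma was given a replicate block, Thy1 and Gna14 passed (adjusted p = 0.0286 each), though nothing in the labels pairs the arrays. With deposited values floored at 16 it called 12, with no filter on dim probes 2, and without uninjured control replicate 2 it called 5. The set call of the immediate early genes was lost without control 3 h replicate 1 (adjusted p = 0.241), without uninjured control replicate 1 (0.0739) or 2 (0.129), without overexpression 3 h replicate 1 (0.0525) or 2 (0.0539), with values floored at 16 (0.139) and with no filter (0.136).

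At 12 h 3 genes passed. Thy1 was 1.84-fold higher (log2 difference 0.88, SE 0.131, adjusted p = 0.00985, 2 arrays against 2), and the early response gene Ier3 was 1.81-fold higher (0.85, SE 0.138, adjusted p = 0.0179). The embryonic globin Hbb-y was 3.55-fold lower (-1.83, SE 0.275, adjusted p = 0.00985), and the adult globin Hba-a1 differed by -1.15 (adjusted p = 0.0636), both being genes of red blood cells. Gadd45a, a DNA damage response gene, differed by 0.88 (adjusted p = 0.0798), Ddit4 by 0.63 (adjusted p = 0.0687), Mkrn3 by -0.61 and the estrogen receptor gene Gper1 by -0.80. Atf3, an injury marker of sensory neurons, differed by 0.46 (SE 0.139, adjusted p = 0.454), and its intensity was above 16 on 2 of 2 arrays against 0 of 2.

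As sets, 5 lists stood higher than other genes at 12 h although none of their members passed, and all 5 lost the call with an estimated correlation. They were cholesterol synthesis (15 genes, median 0.21, adjusted p = 0.000490; adjusted p = 0.191 with an estimated correlation), and amino acid and endoplasmic reticulum stress (18 genes, median 0.15, adjusted p = 0.00106; adjusted p = 0.333 with an estimated correlation). The p53 targets had a median of 0.07 (17 genes, adjusted p = 0.00529; adjusted p = 0.158 with an estimated correlation), and the other HIF targets also had 0.07 (28 genes, adjusted p = 0.00648; adjusted p = 0.260 with an estimated correlation). The HIF glycolysis list had a median of 0.08 (19 genes, adjusted p = 0.0265; adjusted p = 0.337 with an estimated correlation). The values of Mvd (0.37), Cyp51 (0.33), Cebpb (0.45), Herpud1 (0.46), Stc2 (0.33) and Pkm (0.29) show the size of single members. The other 12 lists did not pass. The immediate early list had an adjusted p of 0.0523 and 1 member past the threshold, Ier3. The injury-induced list had a median of -0.03, a mean of 0.02 and an adjusted p of 0.905, so median and mean differed in sign. Adjusted over the list alone, risen members were 1 of the other HIF targets, 2 injury-induced, 3 immediate early, 4 amino acid and endoplasmic reticulum stress, 1 heat shock and 1 p53 gene, and fallen members 1 fibroblast and 2 macrophage markers.

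limma with Benjamini-Hochberg adjustment called these 3 genes of 11151 at 12 h, and 799 had an unadjusted p under 0.05. When limma was given a replicate block, which the labels do not call for, Ddit4 (adjusted p = 0.0450) and Hba-a1 (0.0399) were among further genes that passed. With deposited values floored at 16, Thy1, Ier3 and Hbb-y had adjusted p of 0.104, 0.107 and 0.262, and with an offset of 16 or a plain addition of 50 the count was 0. The difference of Hbb-y was -2.67 with values floored and -1.12 without control 12 h replicate 1 (adjusted p = 0.187). Without uninjured control replicate 1 it called 0, without replicate 2 it called 14, without control 12 h replicate 1 it called 1, and without overexpression 3 h replicate 1 or 2 it called 7. The set calls were lost without uninjured control replicate 1 for the other HIF targets and the amino acid and endoplasmic reticulum stress genes (adjusted p = 0.342 each), without uninjured control replicate 2 for HIF glycolysis (0.187), without control 12 h replicate 1 for p53 targets (0.0579), and without control 12 h replicate 2 for HIF glycolysis (0.366) and the other HIF targets (0.164).

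The last comparison asked whether HIF-1α alters the response to injury. A gene such as Egr1 differed from uninjured by 0.49 at 3 h in control, by 1.24 in knockdown and by 0.33 in overexpression, and its interaction had an adjusted p of 0.780 for knockdown and 0.997 for overexpression. Atf3 differed at 12 h by 0.46 in control, 0.90 in knockdown and 0.28 in overexpression, with adjusted p of 0.701 and 0.924. Both genes were chosen after their values were seen. limma's F test over both times, with Benjamini-Hochberg adjustment, called 0 of 11151 genes for knockdown (648 at an unadjusted p under 0.05) and 0 for overexpression (644). No list passed at either time in either construct. For knockdown at 3 h the immediate early list had a median interaction of 0.16 and the injury-induced list of 0.15. Each had a camera adjusted p = 0.0665 (adjusted p = 0.584 with an estimated correlation). The 100 genes with the largest rise on the overexpression arrays, which enter neither side, were then compared between knockdown and control. Their choice rests on 1 uninjured overexpression array, and at 12 h on 1 array against 1. At 12 h their median change was 0.07 in control and 0.07 in knockdown, and the median difference was -0.03 (camera with the preset correlation, p = 0.764). On the overexpression arrays that chose them it was 0.62. In control 70 of the 100 were higher (camera on the control response, preset correlation, p = 1.07e-05), but the small size of that response limits what the 12 h test can show. At 3 h only 48 of the 100 were higher in control (camera on the control response, preset correlation, p = 0.361). In knockdown 62 of the 100 were higher (camera on the knockdown response, preset correlation, p = 0.0207). The set showed no injury response in control at 3 h, so it cannot show whether knockdown weakens one. Its median change at 3 h was -0.01 in control and 0.05 in knockdown, and the median difference was 0.02 (camera with the preset correlation, p = 0.328). Without overexpression 3 h replicate 1 that median difference was 0.12 (p = 0.00101 with the preset correlation), and without uninjured control replicate 1 it was 0.05 (p = 0.0435). With deposited values floored at 16, 3 genes were called for knockdown and 67 for overexpression, whose uninjured group is 1 array.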

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

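In this part the tests of the interaction at single times, of a trend with intensity, of loss of neurons, of HIF activity in both constructs and of the MHC class I genes were chosen only after the results were seen.

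The response to injury at 3 h differed between overexpression and control cultures for 2 genes, which is what marked them. The neuronal calcium-binding protein Cpne6 was higher by 0.67 in control and differed by -0.64 under overexpression, an interaction of -1.31 (SE 0.220, limma, Benjamini-Hochberg adjusted p = 0.0425). The neuropeptide gene Cartpt differed by -0.32 in control and by 0.83 under overexpression, an interaction of 1.15 (SE 0.187, adjusted p = 0.0425). The uninjured overexpression group is 1 array, and the F test over both times, which was planned, called 0 genes. No group had enough arrays to look for an outlying one.

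The first pattern weighed was the large number of genes that differed between each construct and control. The same arrays were also split otherwise within each time. Among 100 of 108 possible splits for knockdown, only 1, the real one, reached 6653 called genes, and the highest other split gave 2896. For overexpression 1 of 54 splits reached 6161, the highest other giving 2250. This argues against chance spread between these arrays. It cannot test chance differences between cultures, since nothing in the labels says that replicates came from separate cultures. A trend with intensity left between the deposited arrays is argued against as the whole source by cyclic loess, which removes such trends. It changed the numbers of higher and of lower genes and left at least 99.3% of each total count. The normalization done before deposit and the constructs cannot be told apart. A fit on ranks within each array gave at least 92.3% of each count, but the deposited values had equal upper quartiles and maxima and so already followed those ranks, which leaves this test void. Loss of neurons as the whole source is argued against by the pan-neuronal genes, whose lower median of the 2 constructs was -0.28. Of 6 measured 2 fell in knockdown and 3 in overexpression, and 0 rose. Prph fell by 1.38 and by 1.30, and in overexpression Stmn2 fell by 1.54 and Nefm by 0.35, while Uchl1 differed by 0.09 and 0.06 and Stmn3 by 0.03 and -0.17. A smaller loss of neurons stays open. Different embryo pools behind the constructs and the constructs themselves cannot be told apart: of 4 X-inactivation and Y-linked genes measured, 2 were called in knockdown (Xist 0.66 and Ddx3y 0.48) and 1 in overexpression (Xist 0.47), while 59.7% and 55.3% of all genes were called. A virus or culture batch stays open in the same way, and HIF-1α itself stays among the open explanations.

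The second pattern was that knockdown and overexpression, which should move HIF-1α in opposite directions, changed many genes alike. Shared control arrays as the whole source are argued against by a covariance of 0.0953, where the highest of 100 simulations was 0.00315 and the value with the controls split was 0.0898. The mouse Hif1a transcript fell in both, but loss of HIF activity in both is argued against by the HIF target lists, whose lower median under overexpression was 0.93. A difference between the control cultures and both others, in virus or in batch, stays open and was not tested.

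The third pattern was a rise of MHC class I genes under overexpression, a group chosen after its values were seen. Of 21 genes in the group 11 were measured after the filter on dim probes, and of these 8 rose and 1 fell, with a median of 2.57. H2-Q2, H2-T23 and H2-Bl were above 16 on overexpression arrays alone, and H2-Q7 on these and 1 knockdown array. They passed the filter only through the group where they are high, which raises the count and the medians given for class I. H2-Bl was at least 92.3-fold and H2-T23 at least 56.7-fold higher, neither being above 16 on any control array. In knockdown 2 rose and 1 fell with a median of -0.03. An interferon response is argued against by a median of -0.0435 for its list, of which 5 of 11 fell and 1 rose. Of 8 other antigen presentation genes 5 rose and 0 fell, with a median of 0.33, but 6 of the 8 were not above 16 on every control array, where the offset shrinks changes. In knockdown, where class I did not rise as a group, 5 of these 8 rose and 1 fell, with a median of 0.47, and B2m rose by 1.86 against 2.31 in overexpression. The 5 of the 8 that were above 16 on every knockdown array had a median difference of overexpression from knockdown of -0.14 (SD 0.543), against 2.62 for class I. Choosing genes for high values in knockdown pushes this difference down, so it cannot decide whether the whole pathway rose. A rise of the whole pathway stays open. CD-1 mice are outbred, so MHC variants of the embryos under each construct and binding of probes to several class I genes stay open and were not tested.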

How the results depend on the processing

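The tests with an offset of 16, a plain addition of 50, cyclic loess, a filter of 8 arrays and an average over the 3 constructs were chosen only after the data were seen. No called result turned direction. With all probes a named gene was still read on its reported probe, so a turn between probes, as for Espn and Dmkn, could not show there. The 2 construct averages and their counts at each time stayed within 1.5 times of those reported under every setting. Hif1a kept its call in all settings that kept its probe (the filter of 8 arrays removed it), between -0.65 and -0.54 in knockdown and between -0.61 and -0.45 in overexpression with arrays left out.

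Injury counts moved most. With values floored at 16, limma called 12 genes at 3 h, 3 in the interaction with knockdown and 67 with overexpression, and the correlation of the constructs was 0.283 (covariance 0.225). With no filter on dim probes the counts were 2 at 3 h, 7 at 12 h and 1 in the interaction with overexpression (covariance 0.0606), and with all probes the covariance was 0.0877. An offset of 16 gave 0 genes at 12 h, a correlation of 0.278 and a covariance of 0.145. The deposited value plus 50 gave 0 at 12 h and 0.113, and a filter of 16 on 8 arrays gave 0.112. Averaged over the 3 constructs, injury called 4 genes at 3 h and 60 at 12 h. With an estimated correlation 0 of the 68 planned list tests passed. The cause was not tested, except that averaging uses more arrays and that a smaller offset widens dim values. Replicate numbers were not taken as pairs, since deviations of same-numbered arrays correlated at -0.120 to 0.244, over 0.1 in 7 of 21 pairs of groups. Among the 3 control groups they correlated at 0.109, 0.116 and 0.168. A replicate block gave 2 genes at 3 h, Thy1 and Gna14 (adjusted p = 0.0286 each), 8 at 12 h, Ddit4 (0.0450) and Hba-a1 (0.0399) among them, and 2 in the interaction with overexpression. With it the immediate early list passed at 12 h (adjusted p = 0.0376; unblocked, adjusted p = 0.260 with an estimated correlation).

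With each array left out, injury called 0 to 5 genes at 3 h, 0 to 14 at 12 h, 0 to 1 in the interaction with knockdown and 0 to 2 in that with overexpression. The median difference at 3 h of the genes chosen on the overexpression arrays lay between -0.0762 and 0.119, so its sign turned. Uninjured control replicate 2 gave the highest count at both times. Gene lists past the threshold numbered 13 to 22. A group left with 1 array was assumed to vary like the others, and leaving out a lone overexpression array gave no value for its comparisons. Over all fits with an array left out, list results lost 15 calls, gained 19 and kept 1054 as they were, and named genes lost 28, gained 26 and kept 4884. Over the other settings lists lost 21, gained 15 and kept 576, and named genes lost 18, gained 12 and kept 2412. Under overexpression, amino acid and endoplasmic reticulum stress genes passed with values floored at 16 (adjusted p = 0.0350), no filter (0.0116), all probes (0.00170), the replicate block (0.0351), the filter of 8 arrays (0.0384) and some arrays left out, against an adjusted p = 0.528 with an estimated correlation. Injury-induced genes passed with no filter (0.0268) and all probes (0.0373), and NF-κB cytokines with all probes (0.0380) and an offset of 16 (0.0488), against 0.213 and 0.333 with an estimated correlation. Slc16a3 in overexpression lost its call where its other probe was picked.

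Cyclic loess split the overexpression calls into 3222 higher and 2897 lower, 52.7% higher against 46.8% as reported. Raw signal without background correction, median scaling, filters on detection p and a BeadChip block were planned and not run. Signal over background limits dim genes such as Hif1a, where only a bound on the fold can be given.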

Other observations

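The gene groups and the averages over constructs in this part were tests chosen only after the values were seen.

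Averaged over the 3 constructs, the response to axotomy showed more genes than in control cultures alone. At 3 h Egr1, a transcription factor of the first hours after injury, rose by 0.68 (SE 0.0995, limma, Benjamini-Hochberg adjusted p = 0.00396) and Id1, an inhibitor of differentiation factors, fell by 0.73 (SE 0.0769, adjusted p = 8.75e-05). At 12 h 37 genes rose and 23 fell. Ddit3 rose by 0.72 (SE 0.0791, adjusted p = 0.00016), Jun by 0.66 (SE 0.112, adjusted p = 0.00826) and Atf3 by 0.55 (SE 0.0928, adjusted p = 0.00826), while the axon guidance receptor Robo1 fell by 0.49 (SE 0.0848, adjusted p = 0.00849). The amino acid and endoplasmic reticulum stress list was higher at 12 h (5 of 18 rose, adjusted p = 2.93e-09; adjusted p = 0.156 with an estimated correlation), and the injury-induced list did not pass (3 of 26 rose, adjusted p = 0.701). Within knockdown alone 19 genes rose and 34 fell at 12 h, with Ddit3 higher by 1.17, with 2 arrays against 2, and within overexpression, with 1 array against 1, 0 passed (867 at an unadjusted p under 0.05, limma).

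Haemoglobin genes, 2 of which had values below uninjured at 12 h in control, were higher in both constructs. Hbb-y rose by 2.15 in knockdown and 2.23 in overexpression and Hba-a1 by 1.99 and 1.71, and 4 of 5 measured rose in each. Of 6 other red blood cell genes 2 rose and 1 fell in knockdown, and 1 rose and 2 fell in overexpression. Of 17 genes of synaptic vesicles 6 rose and 8 fell in knockdown, and 4 rose and 10 fell in overexpression. Vamp2 fell by 3.00 in knockdown and rose by 0.34 in overexpression, the vesicular glutamate transporter Slc17a6 fell by 1.55 and rose by 0.28, and Cplx2 rose by 0.37 and fell by 1.69. Of 8 genes for HIF subunits and their regulators, Hif1a included, 5 fell and 0 rose in knockdown, and 3 rose and 2 fell in overexpression. The prolyl hydroxylase Egln3, itself a HIF target, fell by 1.19 and rose by 0.68, and Vhl, which marks HIF-1α for destruction, fell by 0.70 in knockdown and differed by 0.22 in overexpression, which did not pass (adjusted p = 0.0962).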
